A study of Danio rerio with 20 samples.

How the data were processed

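Total RNA of samples given as zebrafish testis was measured on 20 single-colour Affymetrix whole-transcript arrays. The samples were adult males of the AB strain, 1 year old per the labels, and fell into 4 groups of 5. Their ancestors, the F0 fish, were kept for 1 h in water with the dioxin TCDD at 50 pg/ml or with the vehicle DMSO, at 3 and again at 7 weeks after fertilization. The F1 and F2 males themselves were not exposed. The labels call the 5 males of a group biological replicates. Which families they came from is not given in the sources used here, so p-values measure the spread between males whose kinship is unknown.

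The values are those the authors deposited, on a log2 scale as judged from their range of 1.17 to 14.33. Affymetrix Expression Console made them, per the submitters' processing notes. Its version, the summary algorithm, the normalization and the genome build are not given in the sources used here. The table held 75212 features, called probe sets below. Of these, 20856 had 1 gene symbol in the array annotation, 805 had several and 53551 had none, and 19298 different genes were named by the first kind. Probe sets with several symbols were never named. Symbols were updated through Entrez identifiers where the RefSeq gene table of assembly GRCz12tu allowed it, which changed 1 symbol, and 20323 of the 20856 probe sets matched a gene of that table. No coordinates are given, because the build behind the array annotation is not stated. Control probe sets are not marked in the files, so all 75212 features were tested, although the plan had been to leave controls out. In all, 9270 rows repeated the values of an earlier row on every array, leaving 65942 distinct profiles. The identical rows were counted as separate features, and the number of distinct profiles is given beside the calls between the F2 lineages.

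The array medians formed 2 sets separated by 0.359 on the log2 scale. The higher set held replicates 1 to 4 of both F1 groups (8 arrays, medians 6.47 to 6.58). The lower set held replicate 5 of both F1 groups and all F2 arrays (12 arrays, medians 6.01 to 6.11). The labels do not explain this split. It was therefore treated as a batch of arrays processed apart, and each count was recomputed with the set as a covariate. The lineages are balanced over the sets within each generation. In contrasts between lineages the covariate therefore changes the spread and leaves the fold changes as they are. Counts within F1 were also made in the higher set alone, and those within F2 and between the DMSO lineages in the lower set alone. No 2 arrays were identical, and the closest pair differed by a mean of 0.255 on the log2 scale. The number of arrays limits the precision of every value.

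Differences between groups were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values. A single linear model of the 4 group means was fitted to all 20 arrays (lmFit and eBayes with default settings, 16 residual degrees of freedom). Tests were 2-sided and p-values were adjusted by the Benjamini-Hochberg method over all 75212 features. A feature was called at an adjusted p under 0.05. The 4 contrasts were TCDD against DMSO lineage in F1, the same in F2, the difference between these effects (F2 minus F1), and F2 DMSO against F1 DMSO. Fold changes are differences of mean log2 values with the standard error (SE) of the moderated fit, and group values are means ± SD.

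Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, which compares the genes of a list with all other genes. Each of the 19298 genes was represented by its probe set with the highest mean. The 39 lists, 17 of cell types and 22 of pathways, held 11 to 67 measured genes each and 1013 different genes in all. Adjustment was over the 39 lists. Each test was repeated with a correlation estimated from the data and with fry, which asks whether the genes of a list move in a shared direction on balance and does not compare them with other genes. List scores per array were the mean over the list's genes of the log2 value minus the gene's mean over the 20 arrays, after the offset between array sets was removed. They were compared with an exact permutation test within array sets (140 assignments in F1, smallest possible p 0.0143, and 252 in F2, smallest possible p 0.00794).

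The contrasts, the tests, the lists, the rule for naming genes and the first group of other settings were fixed before the data were examined. In each contrast between lineages the naming rule took, among called probe sets with 1 symbol whose arrays did not overlap between the groups, the 10 largest rises and the 10 largest falls. For the control contrast and the difference of effects it took 5 of each, without the requirement of no overlap for the latter. Where fewer than 10 probe sets with 1 symbol were called, the 10 with the smallest p were named as not having passed. For each list called in F1 or F2 it added up to 4 members with the smallest p, with any probe set called in both generations and, in every contrast, 20 marker genes of dioxin response, testis cells and other organs. Of these markers, 15 were measured under a symbol or unambiguous synonym, and cyp1a, ar, nanos2, fabp10a and hbaa1 were not matched. Genes named outside the rule are said to be so.

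On simulated data with the real means and spreads and 50 features changed at each size, the F2 test called 2%, 28%, 78% and 98% of the features changed by 0.5, 1, 2 and 4 on the log2 scale among 75212. For the F1 test these shares were 2%, 32%, 78% and 98%. Of the unchanged features, 2 were called in the F2 simulation and 6 in the F1 simulation. In the F2 simulation, 2 of 2 lists that had been shifted were called in the right direction and 0 of 37 others were called. The simulated noise was independent between features, unlike that of real arrays.

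The other settings fixed at that point were other thresholds, 1 probe set per gene, quantile normalization, median centring of arrays, removal of probe sets below the 30th percentile of the mean, eBayes with trend and robust estimation, array weights, a fit of only the groups compared, the replicate number as a block, the mean over a gene's probe sets, and leaving out each array. Settings added after seeing the data were the array set as a covariate, fits within 1 array set, identical rows counted once, the permutation test of list scores, and 2 fits that addressed tissue of other organs. The first of these used the intestine, liver, exocrine pancreas and skeletal muscle scores with the array set as covariates, and the other left out the 4 arrays with the highest intestine score. For the tests of explanations, each expectation was written down after the pattern had been seen. Measures were added or read anew after the first had given its result, and both are given. For the F2 calls and organ tissue, the size of the fold changes was added, and for the DMSO lineages and a shift of whole arrays a stricter limit. For the F1 lists and organ tissue, the first count (17 of 28, under the limit of 1/1.5) was repeated without the organ lists and for the lower lists alone. The 23 lists called without F1_TCDD replicate 2 were first read as evidence against that array as the source, a reading dropped because other splits of the samples called as many, and its list sizes and testis markers were added. The neighbours among the F2 calls were first read as evidence for linked differences. They were counted again with those within 5 positions that went the same way counted as 1, whatever their gene symbols. Counts of 0, first read as not excluding chance, were dropped from that reading. Other splits of the samples were drawn 100 times with a fixed seed, the real split included. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.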

Results

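RNA of samples given as testis was measured in 20 zebrafish males, 5 from each of 4 groups. The groups were the F1 and F2 descendants of fish exposed to TCDD, a dioxin that acts through the aryl hydrocarbon receptor, and the F1 and F2 descendants of fish given the vehicle DMSO. Each array gave 75212 log2 values, and the number of arrays limits the precision. The array of F1_TCDD replicate 2 went against the tissue its label gives. The median of 11 Sertoli, Leydig and germ cell markers was 6.39 in it, near the array's own median of 6.58, and 9.66 to 11.6 in the other 19 arrays, and each marker was lower than in any other array. Array medians fell into a higher set of 8 F1 arrays (6.47 to 6.58) and a lower set of 12 arrays (6.01 to 6.11) that held replicate 5 of both F1 groups and all F2 arrays. Each lineage therefore had 4 arrays in the higher set within F1, and both F2 lineages lay wholly in the lower set. Within F1 the sets differed by a median of 0.469 per feature, and counts of calls are also given with the set as a covariate. Between lineages, which are balanced over the sets, that covariate changes the spread only and not the fold changes.

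**Figure D1:**
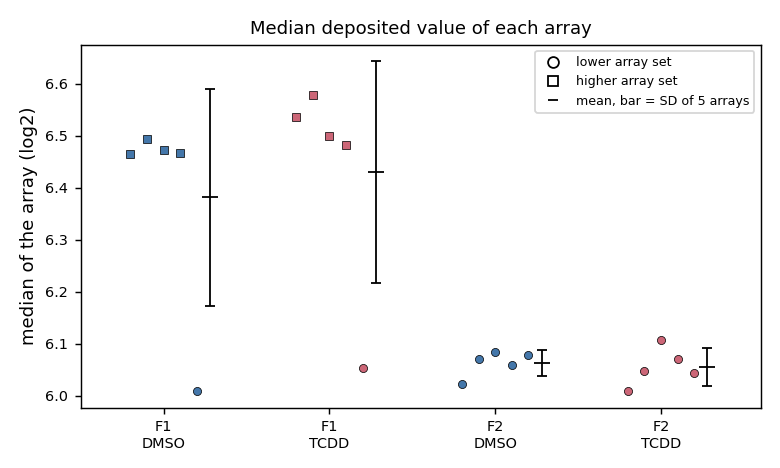
Median log2 value of each array (vertical axis, log2) by group (horizontal axis), with squares for the higher and circles for the lower array set and bars for the mean and SD of 5 arrays. The 8 higher F1 arrays lie at 6.47 to 6.58 and the 12 others at 6.01 to 6.11.

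The first comparison asked whether the testis of F1 males differed between the TCDD and DMSO lineages. Genes of germ cell differentiation had lower values in the TCDD lineage (n = 5 arrays per group). All 19 measured meiosis genes were lower, with a median log2 fold change of −1.27. So were 20 of 21 spermatid and sperm genes (median −1.22) and 44 of 46 genes of the axoneme and cilia (−1.24). Genes of immune cells, matrix and some other organs were higher, among them all 21 liver genes (median 1.19), all 14 intestine genes (1.27) and all 15 genes of the exocrine pancreas (1.38), while 14 of 20 skeletal muscle genes were lower (−0.12). No single gene passed the test, and the list calls depended on how the correlation between genes was treated. A large part of the size of these differences came from 1 array, F1_TCDD replicate 2. Its meiosis score was −3.58, while the other 4 F1_TCDD arrays lay between −0.486 and 0.941. Without that array the medians were −0.403 for meiosis, −0.409 for spermatids and sperm, −0.457 for the axoneme, 0.537 for liver, 0.443 for intestine and 0.778 for exocrine pancreas.

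Among the meiosis genes, sycp3 of the synaptonemal complex was at 11.30 ± 0.46 in DMSO and 10.04 ± 1.79 in TCDD arrays (mean ± SD, n = 5), a log2 fold change of −1.27 ± 0.61 (SE). Values were −1.57 ± 0.77 for sycp2, −1.08 for spo11, which makes meiotic DNA breaks, and −1.60 for hsf5. The dynein heavy chain gene dnah5 had −1.61 ± 0.65, the ciliary assembly gene zmynd10 −1.39 ± 0.65, dnah10 −1.24 and ift172 −1.12. Of the sperm list, spata17 had −1.36 ± 0.48, spag6 −1.75 ± 0.79, tsga10 −1.25 and meig1 −1.03. The mitosis list had 36 of 37 genes lower (median −0.94), among them the kinesin genes kif11 (−1.08 ± 0.47), kif20a (−1.11) and kif23 (−1.24), and ndc80 of the kinetochore (−1.19). All 18 genes of the piRNA pathway were lower (median −0.91), with tdrd7a at −1.65 ± 0.83, gtsf1 at −1.24, henmt1 at −0.84 and tdrkh at −0.75. Of the Sertoli cell markers 10 of 11 were lower (median −0.76), including sox9a (−0.76 ± 0.38), cldn11a (−1.03), dmrt1 (−0.94) and inha (−1.11). Of the 58 named genes with lower values in F1, 40 were under 1/1.5 of their size without F1_TCDD replicate 2. Values were then −0.626 for sycp3, −0.556 for sycp2, −0.445 for spo11, −0.536 for hsf5, −0.853 for dnah5, −0.652 for zmynd10, −0.600 for dnah10, −0.502 for ift172, −0.807 for spata17, −0.694 for spag6, −0.636 for tsga10 and −0.474 for meig1. They were −0.624 for kif11, −0.550 for kif20a, −0.628 for kif23, −0.603 for ndc80, −0.486 for tdrd7a, −0.440 for gtsf1, −0.357 for henmt1 and −0.332 for tdrkh. The Sertoli median was −0.143, with cldn11a at −0.313, dmrt1 at −0.143, inha at −0.0501 and sox9a at −0.769. The proteasome list had 38 of 41 genes lower by a small amount (median −0.28), for example psmc1a (−0.79) and psmb3 (−0.47). In the list of DNA methylation and chromatin, 19 of 23 genes were lower (median −0.33). Its DNA methyltransferase genes dnmt3ba and dnmt3bb.3 had −0.70 ± 0.28 and −0.97, uhrf1 −0.78, and the histone methyltransferase gene ezh1 went the other way (0.61).

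These 8 lists were called lower by camera with the preset correlation, with adjusted p = 2.45e-10 for the axoneme, 2.02e-08 for mitosis, 1.08e-06 for spermatids and sperm, 1.75e-06 for meiosis, 9.60e-06 for the piRNA pathway, 1.60e-05 for the proteasome, 0.00500 for DNA methylation and chromatin and 0.0202 for Sertoli cells. With an estimated correlation none was called. The adjusted p was then 0.485 for DNA methylation and chromatin and 0.480 for the other 7. With array weights 0 of the 8 were called. Without F1_TCDD replicate 2 Sertoli cells (adjusted p = 0.694) and DNA methylation and chromatin (0.0727) lost the call, the latter with a median of −0.131. Medians without it were −0.336 for mitosis, −0.294 for the piRNA pathway and −0.158 for the proteasome, and the middle value of the 8 went from −0.924 to −0.315. Without F1_DMSO replicate 5 Sertoli cells (adjusted p = 0.0986) lost the call. Without F1_TCDD replicate 5 the medians were −0.191 for DNA methylation and chromatin and −0.172 for the proteasome.

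The 20 lists with higher values were called with the preset correlation, and 0 of them with an estimated one (adjusted p from 0.480 to 0.514). Immediate early genes had 28 of 33 members higher (median 0.44, adjusted p = 2.45e-07), among them the transcription factor genes atf3 (0.83 ± 0.25), junbb (1.06 ± 0.36) and klf4 (1.07), and btg2 (0.94 ± 0.36). Complement and interferon genes had 34 of 41 higher (median 0.42, adjusted p = 2.79e-05), with the complement gene c7b at 1.85 ± 0.72, irf1b at 1.39 ± 0.55, the class I histocompatibility gene mhc1uba at 2.51 ± 1.01 and psmb8a at 0.59. Macrophage and granulocyte genes (15 of 18 higher, median 0.62, adjusted p = 0.00293) included lcp1 (0.79), and lymphocyte genes (11 of 14, median 0.39, adjusted p = 0.00470) included zap70 (0.63), cd4-1 (0.43) and, lower, rag2 (−1.16). Matrix genes had 36 of 43 higher (median 0.33, adjusted p = 2.61e-05), with the collagen genes col1a2 at 0.89 ± 0.36, col1a1a at 1.00 ± 0.44 and col6a3 at 0.70. Smooth muscle and myoid genes (11 of 12, median 0.40, adjusted p = 0.000628) included acta2 (0.76 ± 0.35), cnn1b (0.76) and desmb (1.21). Endothelial genes (14 of 20, median 0.21, adjusted p = 0.00592) included kdr (0.43) and she (0.57), and erythrocyte genes (11 of 12, median 0.85, adjusted p = 0.000123) included gata1a (1.08) and hemgn (0.92). The adjusted p with an estimated correlation was 0.480 for each of these 8 lists. Without F1_TCDD replicate 2 the medians were 0.148 for complement and interferon (26 of 41 higher), 0.241 for macrophages, 0.208 for lymphocytes, 0.215 for matrix, 0.257 for smooth muscle and myoid and 0.0461 for endothelium. Without F1_DMSO replicate 5 they were 0.283 for immediate early genes, 0.266 for complement and interferon, 0.395 for macrophages, 0.190 for matrix, 0.260 for smooth muscle and myoid and 0.0836 for endothelium. Without F1_TCDD replicate 5 macrophages (adjusted p = 0.125), lymphocytes (0.0522) and smooth muscle and myoid (0.0522) lost the call. The immediate early median was 0.284 without F1_TCDD replicate 4, and the endothelial one 0.321 without F1_DMSO replicate 2 and 0.389 without F1_TCDD replicate 5.

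The other 12 of these lists were likewise called with the preset correlation only. Of the organ lists, exocrine pancreas (adjusted p = 0.000496) held ela2l at 2.82 ± 1.32 and cpa4 at 1.90 ± 1.00. The intestine list (adjusted p = 0.00124) held fabp6 at 2.36, cdx1b at 2.09 ± 1.24 and cdh17 at 2.02 ± 1.22. The liver list (adjusted p = 0.000158) held hp at 1.26, hpxa at 1.69 and rbp4 at 0.64. Kidney and interrenal genes (12 of 14 higher, median 0.33, adjusted p = 0.0119) included slc20a1a (1.45 ± 0.53) and atp1a1a.4 (1.75), and adipocyte genes (10 of 12, median 0.66, adjusted p = 0.0119) included pparg (0.88) and fabp4a (0.62). Xenobiotic metabolism had 22 of 24 genes higher (median 0.65, adjusted p = 0.000473), with sult1st1 at 1.16, and the antioxidant list of Nrf2 targets 23 of 25 (median 0.21, adjusted p = 0.00282), with gpx1b at 1.85 ± 0.74 and nfe2l2a at 0.57. Fatty acid metabolism (33 of 43, median 0.34, adjusted p = 0.00256) included lpla (1.14) and elovl4a (−0.78), and cholesterol synthesis (23 of 30, median 0.31, adjusted p = 0.00465) insig1 (1.27 ± 0.56), srebf2 (0.68) and stard4 (0.62). Ribosomal protein genes were higher by a small amount in 57 of 59 cases (median 0.19, adjusted p = 1.60e-05), such as rpsa (0.30) and rpl3 (0.22). Clock genes (23 of 32, median 0.25, adjusted p = 0.00148) included nr1d1 (1.09) and bmal1a (−0.51), and hormone receptors (14 of 18, median 0.29, adjusted p = 0.0149) thrb (0.56). With an estimated correlation it was 0.485 for ribosomal proteins, 0.514 for cholesterol synthesis and 0.480 for the other 10. Of the 76 named genes with higher values in F1, 37 were under 1/1.5 of their size without F1_TCDD replicate 2. With array weights 3 of the 20 lists were called. Without F1_TCDD replicate 2 the middle value of their medians went from 0.397 to 0.215, and cholesterol synthesis (median −0.0278, adjusted p = 0.920), fatty acid metabolism (median 0.0702, 0.0805) and hormone receptors (median 0.109, 0.0645) lost the call. The ribosomal median was then 0.0280 (41 of 59 higher), that of xenobiotic metabolism 0.215, of the Nrf2 targets 0.102, of the clock 0.132 and of adipocytes 0.382. Without F1_DMSO replicate 5 the middle value was 0.263, the ribosomal median −0.00647, and hormone receptors (adjusted p = 0.0782) lost the call. Medians without it were 0.589 for liver, 0.787 for pancreas, 0.399 for xenobiotic metabolism, 0.111 for the Nrf2 targets, 0.149 for cholesterol synthesis, 0.189 for fatty acid metabolism and 0.143 for the clock. Without F1_TCDD replicate 5 10 of the 20 were called, and liver (adjusted p = 0.0814), pancreas (0.0663), adipocytes (0.0554), kidney and interrenal (0.243), Nrf2 targets (0.162), xenobiotic (0.0911) and fatty acid metabolism (0.0606) were among those lost, while the ribosomal median was 0.356. The pancreas median was 0.741 without F1_TCDD replicate 1 and 2.2, 2.33 and 2.08 without F1_DMSO replicate 1 and F1_TCDD replicates 3 and 4. Without F1_TCDD replicate 3 it was 1.89 for liver, 1.07 for xenobiotic metabolism and 0.330 for the Nrf2 targets, without F1_DMSO replicate 3 2.05 for intestine, and without F1_TCDD replicate 1 0.104 for ribosomal proteins.

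Lists not called in F1 were oocyte and ovary (median −0.48, adjusted p = 0.0855), glycolysis (0.15, 0.0920), Wnt, TGF-beta and IGF signalling (0.07, 0.0920), the aryl hydrocarbon receptor battery (0.17, 0.0957), the citrate cycle and respiratory chain (0.04, 0.153), spermatogonia (−0.56, 0.192), Leydig cells (−0.64, 0.211), retinoids (0.12, 0.356), the unfolded protein response and heat shock (0.01, 0.541), DNA damage and apoptosis (−0.14, 0.569) and skeletal muscle (−0.12, 0.640). In all, 28 of 39 lists were called in F1, 20 higher and 8 lower, and the same number with the array set as a covariate. Within the 8 arrays of the higher set 18 were called, and without F1_TCDD replicate 5 also 18. With array weights 3 were called, all higher, and 17 with the array set and the scores of the intestine, liver, exocrine pancreas and skeletal muscle lists (the organ scores) as covariates, 9 higher and 8 lower, of which 16 were among the 28. By camera with an estimated correlation, by fry (smallest adjusted p = 0.417) and by the exact permutation test of list scores (smallest adjusted p = 0.499) the count was 0, and 1 list had an unadjusted exact p under 0.05. With 140 assignments the permutation test could call a list only if at least 12 had a low exact p, the smallest possible being 0.0143. It is therefore a weak test where few lists differ, but most exact p were not low either. They were 0.0429 for immediate early genes, the lowest, 0.157 for spermatids and sperm, 0.186 for the axoneme, 0.214 for meiosis, 0.357 for intestine and 0.457 for liver.

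The 10 named probe sets with the smallest p in F1, none of which passed, were led by the odorant receptor gene or90b2 at −2.09 ± 0.39 (DMSO 7.77 ± 0.28, TCDD 5.68 ± 0.89). The sphingomyelin synthase gene sgms2a had −1.52 ± 0.33, the lysyl oxidase-like gene loxl2a 1.28 ± 0.29 and the chemokine receptor gene ccr11.1 −2.26 ± 0.53. The others were or90b1 (−1.16 ± 0.25), si:dkey-21o22.2 (−1.12 ± 0.25), ppef1 (−1.36 ± 0.32), pcdh8 (−1.26 ± 0.30), spra (−1.21 ± 0.30) and or137-9 (−1.39 ± 0.36), all with adjusted p = 0.583 in limma. Of the dioxin response markers, cyp1b1 had 0.26 ± 0.21 and ahrra 0.04 ± 0.17. Somatic markers had −0.93 (gsdf), −0.72 (amh), −1.45 (insl3), −0.90 (star), −1.20 (cyp17a1), −0.69 (cyp11c1) and 0.30 (cyp19a1a). Germ cell markers had −1.19 (ddx4), −1.41 (dmc1), −1.41 (cimap1b), −1.37 (tekt1) and −0.63 (zp3b), and adjusted p for these markers was 0.583 or more. Without F1_TCDD replicate 2 cyp1b1 was at 0.0634 and sycp3 at −0.626, gsdf (0.161), amh (0.388) and star (0.0283) turned sign, and values were −0.166 for insl3, −0.434 for cyp17a1, −0.102 for cyp11c1, −0.283 for ddx4, −0.403 for dmc1, −0.321 for cimap1b and −0.459 for tekt1. The probe set that stood for loxl2a in the matrix list, which has another identifier, had 0.94. In F1_TCDD, gsdf spanned a wide range, at 12.16 ± 2.45 against 13.09 ± 0.25 in DMSO arrays.

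By limma 0 features were called between the F1 lineages, with 5363 at an unadjusted p under 0.05 and a smallest adjusted p of 0.506. With the array set as a covariate the count was also 0 (9295 unadjusted, smallest adjusted p = 0.0572), and within the 8 arrays of the higher set 0 (smallest adjusted p = 0.690). It was 7 with array weights, 1 after median centring, and 1 without F1_TCDD replicate 1, namely or90b2 at −2.47 (adjusted p = 0.0370). Over all genes 0 list members were called, and 0 when adjusted over the list alone.

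The same question was asked of F2. Here 11 named genes passed the test, and in each all 5 TCDD arrays lay on one side of all 5 DMSO arrays. The chemokine receptor gene ccr11.1 (probe set 13029673) fell from 9.97 ± 0.55 in the DMSO to 4.69 ± 0.61 in the TCDD lineage (mean ± SD, n = 5), a log2 fold change of −5.28 ± 0.53 (adjusted p = 0.000218, and 0.000302 with the array set as a covariate). For mrps22 of the mitochondrial ribosome, probe set 13023859 rose from 3.17 ± 0.30 to 5.16 ± 0.42, by 1.99 ± 0.25 (adjusted p = 0.00127). It stood at 5.14 and 4.99 in the F1 lineages. This probe set was dim, and with 1 probe set per gene no rise was called for mrps22. The uncharacterised gene LOC100006764 (13125972) fell from 7.60 ± 0.54 to 3.11 ± 0.24, a change of −4.49 ± 0.54 (adjusted p = 0.000813).

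**Figure D2:**
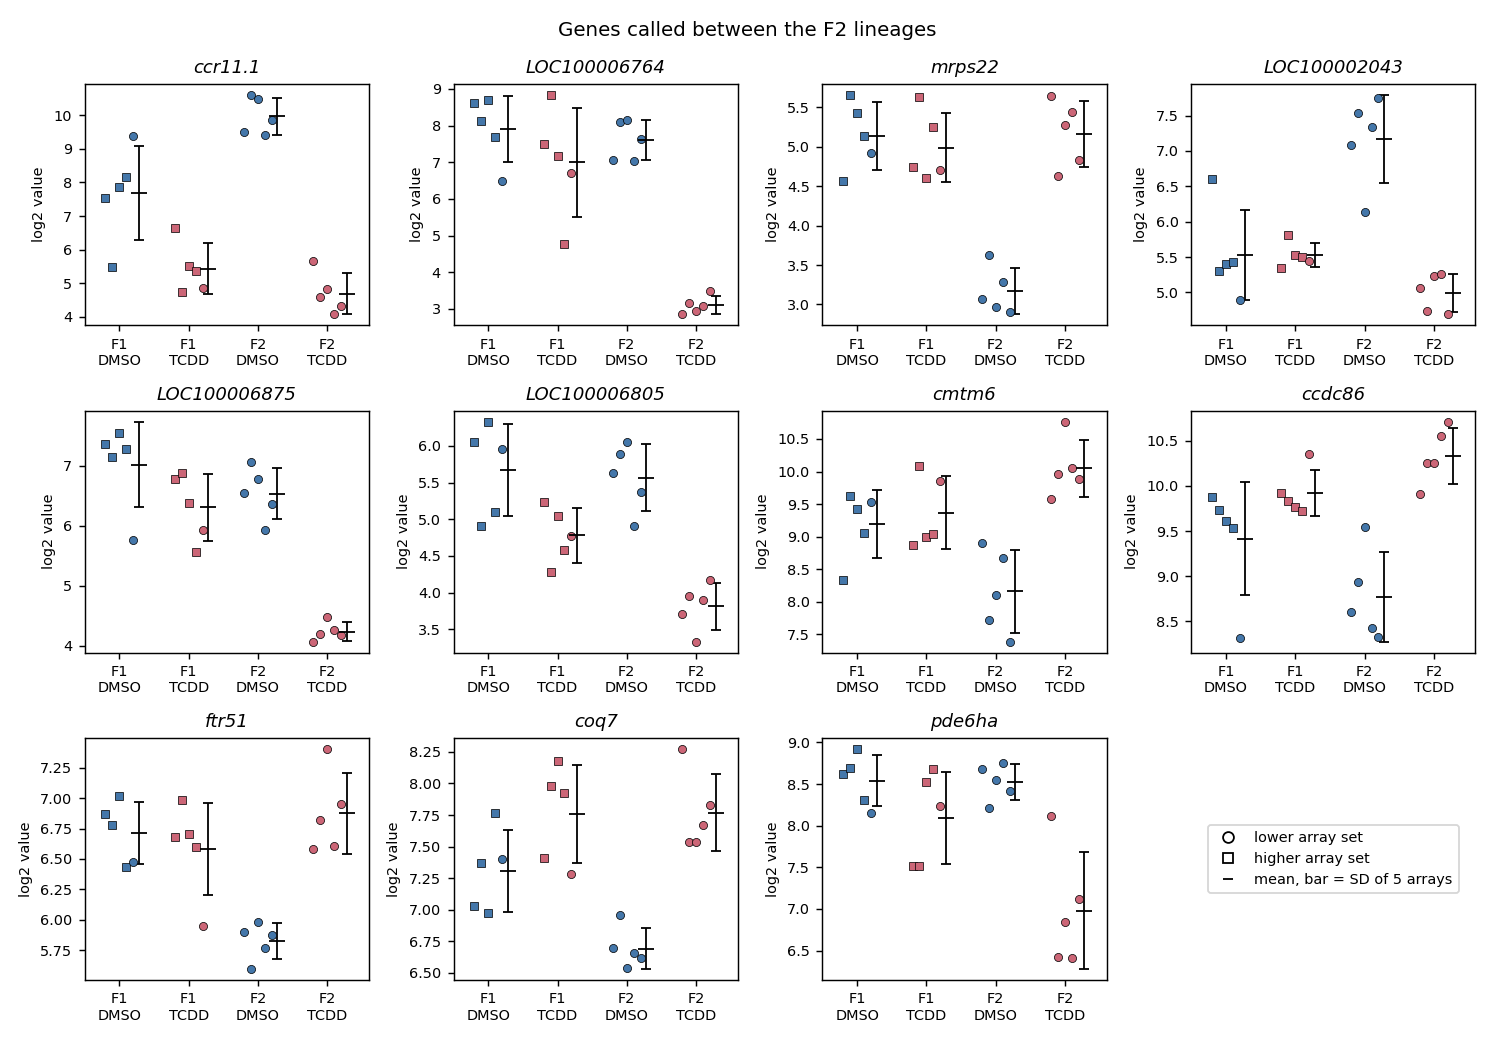
Log2 values (vertical axis) of the 11 named genes called between the F2 lineages, by group (horizontal axis), with 1 point per array, squares for the higher and circles for the lower array set, and bars for the mean and SD of 5 arrays. In F2 the arrays of the lineages are apart for every gene, as for ccr11.1 with means of 9.97 and 4.69.

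Other genes that fell were LOC100006875 (13125990, −2.30 ± 0.31, adjusted p = 0.00284), LOC100002043 (13028470, −2.18 ± 0.29, adjusted p = 0.00284), LOC100006805 (13125979, −1.76 ± 0.28, adjusted p = 0.0119) and the phosphodiesterase 6 gene pde6ha (13217794, −1.54 ± 0.29, adjusted p = 0.0475). Genes that rose were cmtm6 (13041105, 1.89 ± 0.33, adjusted p = 0.0240), ccdc86 (12958412, 1.56 ± 0.27, adjusted p = 0.0249), the ubiquinone synthesis gene coq7 (13218895, 1.08 ± 0.20, adjusted p = 0.0375) and the finTRIM gene ftr51 (13184828, 1.05 ± 0.19, adjusted p = 0.0359). Of the 23 settings that gave a value for it, ccr11.1 was called in 23, while ccdc86 and cmtm6 were called in 14, coq7 and ftr51 in 12 and pde6ha in 7. LOC100006764, LOC100006875 and LOC100002043 were called in 23 of 23, mrps22 in 22 of 22 and LOC100006805 in 20 of 22. The setting that gave no value for mrps22 and LOC100006805 was the removal of dim probe sets, which took out both. With 1 probe set per gene, the one with the highest mean, the 5 calls were all lower, so no rise was called for mrps22. The 15 marker genes did not pass in F2, with values from −0.37 (amh) to 0.66 (cyp17a1) and adjusted p = 1.

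In all, 72 features were called in F2, 51 higher and 21 lower, with 3082 at an unadjusted p under 0.05. They made up 51 distinct profiles, and 61 of the 72 had no gene symbol. Absolute log2 fold changes ran from 0.81 to 5.28 with a median of 2.16. The lineages did not overlap in any of the 72 called features, nor in 1.30% of all features, where chance gives 0.794%. The count was 120 with the array set as a covariate (80 higher, 40 lower) and 96 within the 12 arrays of the lower set, as in a fit of the F2 groups alone. With array weights it was 504, and with 1 probe set per named gene 5, all lower. It was 31 without F2_DMSO replicate 2, 33 without F2_DMSO replicate 3, 118 without F2_TCDD replicate 1, and 44, 36 and 34 without F2_TCDD replicates 2, 4 and 5.

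Among the lists in F2, 8 were called with the preset correlation and 0 with an estimated one, where the adjusted p was 0.984 for each of the 8. Skeletal muscle genes had lower values in the TCDD lineage (16 of 20, median −0.71, adjusted p = 7.65e-05), among them tropomyosin tpma (−1.35 ± 0.55), parvalbumin pvalb2 (−1.75 ± 0.79) and myhz1.1 (−0.68), with the actin gene acta1b at 1.19 ± 0.41. Axoneme genes were higher in 43 of 46 cases (median 0.37, adjusted p = 8.47e-05), for example rsph4a (1.11) and spef1 (0.98), as were 20 of 21 spermatid and sperm genes (median 0.33, adjusted p = 0.00341), including ropn1l (1.09), tekt2 (0.59), izumo1 (0.57) and tekt3 (0.46). The citrate cycle and respiratory chain list had 47 of 67 genes higher by a small amount (median 0.07, adjusted p = 0.000992), with ndufb2 at 0.69 ± 0.23, ndufv3 at 0.56, sdhc at 0.40 ± 0.17 and ndufb10 at 0.39. Cholesterol synthesis had 24 of 30 higher (median 0.33, adjusted p = 0.00341), with insig1 at 0.73, ebp at 0.72, tm7sf2 at 0.58 and abca1a at 0.47. Endothelial genes had 16 of 20 higher (median 0.14, adjusted p = 0.0105), with etsrp at 0.58 ± 0.25, egfl7 at 0.40 and kdrl at 0.37. Complement and interferon genes had 31 of 41 lower (median −0.23, adjusted p = 0.0105), with mhc1uba at −3.79 ± 1.01 (adjusted p = 0.295), irf1b at −0.81, isg15 at −0.67 and nfkbiab at −0.52. Liver genes had 19 of 21 lower (median −0.79, adjusted p = 0.0131, and 0.0541 with the array set), with c3a.1 at −1.15, serpina1l at −0.96, hp at −0.80 and vtg2 at −0.73.

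Like camera with an estimated correlation, fry (smallest adjusted p = 0.995) and the exact permutation test (smallest adjusted p = 0.992) called 0 lists. For any list to pass the permutation test at least 7 need a low exact p, and 0 had one under 0.05. With the array set 7 lists were called. With the organ scores as covariates 11 were, all higher and 4 of them among the 8, so complement and interferon and spermatids and sperm lost the call, as did skeletal muscle and liver, whose own scores were covariates. The liver list lost the call without F2_DMSO replicate 4 (median −0.246) or 5 (−0.257) and without F2_TCDD replicate 1 (−0.381), 2 or 5. Complement and interferon lost it without F2_DMSO replicate 4 (−0.118) and without F2_TCDD replicates 1 (−0.110), 2 (−0.138) and 5 (−0.123), and endothelium without F2_DMSO replicates 1 (0.0730) and 4 (0.0586) and F2_TCDD replicate 4 (0.0702). Cholesterol synthesis had a median of 0.00649 and the respiratory chain −0.0120 without F2_TCDD replicate 3, and spermatids and sperm had 0.0796 and the axoneme 0.134 without F2_TCDD replicate 1, each without a call. Spermatids and sperm also lost it without F2_DMSO replicate 4 (0.208) and F2_TCDD replicate 2 (0.207), and the respiratory chain without F2_DMSO replicate 2 (0.0497). Larger sizes were found without F2_DMSO replicate 1 for spermatids and sperm (0.561) and the axoneme (0.613), and without F2_TCDD replicate 3 for these (0.564 and 0.649), liver (−1.29), skeletal muscle (−1.08) and complement and interferon (−0.377). They were also found without F2_DMSO replicate 5 for skeletal muscle (−1.18), F2_TCDD replicate 4 for complement and interferon (−0.438) and F2_DMSO replicate 3 for endothelium (0.239). The respiratory chain had 0.0460 without F2_DMSO replicate 3, 0.183 without F2_DMSO replicate 4, and 0.107, 0.120 and 0.109 without F2_TCDD replicates 1, 2 and 5. Of the 8 lists, 4 were called without F2_DMSO replicate 4 and 4 without F2_TCDD replicate 1, 5 without F2_TCDD replicate 2, and 6 without F2_TCDD replicate 3 or 5. Without F2_DMSO replicates 1, 2 and 5 and F2_TCDD replicate 4, 7 were called each time. Over all genes 0 list members were called, and 0 when adjusted over the list alone. The other 31 lists had adjusted p from 0.0839 (exocrine pancreas) to 0.973 (matrix) and medians from −0.71 (exocrine pancreas) to 0.18 (Leydig cells). In 7 of them, lymphocytes, adipocytes, kidney and interrenal, the Nrf2 targets, hormone receptors, the piRNA pathway and DNA damage, the median, the mean and the test differed in sign.

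**Figure D3:**
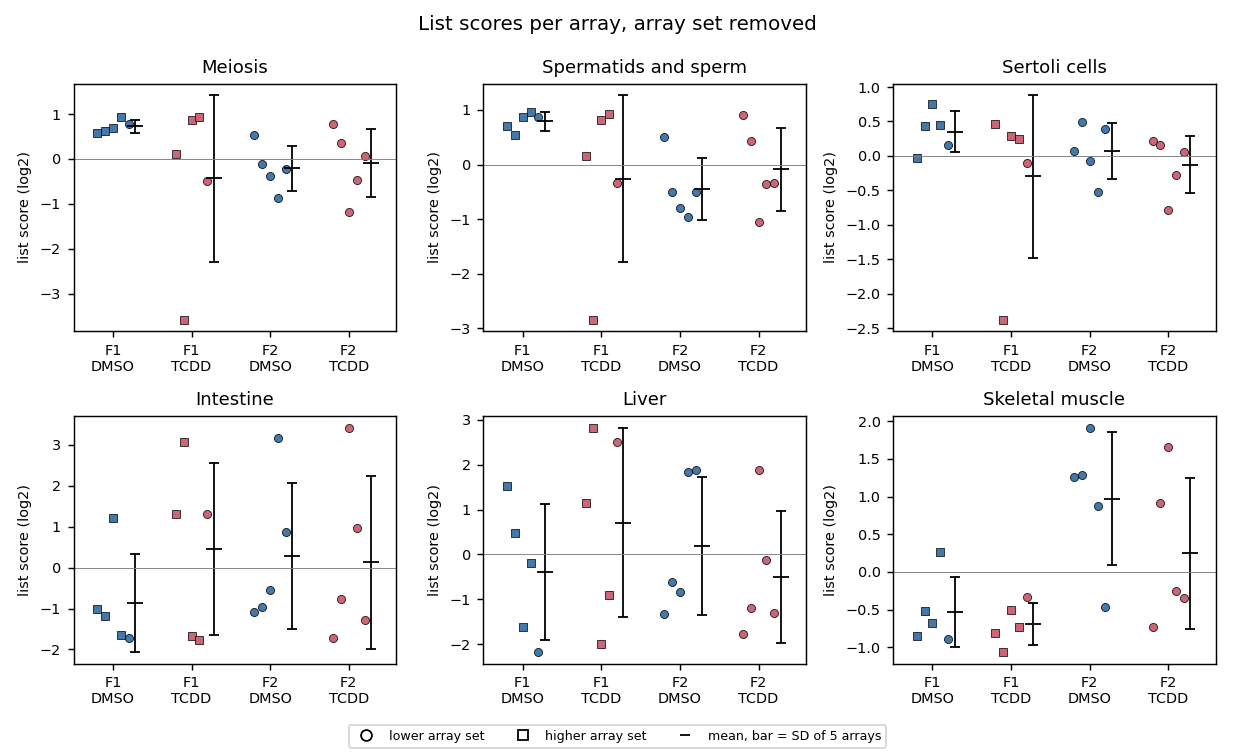
Scores of 6 gene lists per array (vertical axis, mean log2 value of the list's genes relative to the 20 arrays, array set removed) by group (horizontal axis), with bars for the mean and SD of 5 arrays. Arrays of a group lie far apart, with intestine scores from −1.71 in F2_TCDD replicate 1 to 3.43 in F2_TCDD replicate 3.

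Whether the lineage difference itself differed between generations was tested as F2 minus F1. The largest evidence for single genes was for mrps22, with a difference of 2.15 ± 0.35 (adjusted p = 0.127, and 0.0875 with the array set), which did not pass. Next came LOC100002043 (−2.18 ± 0.41, adjusted p = 0.232), mrpl47 of the mitochondrial ribosome (2.52 ± 0.49, 0.240) and LOC100006764 (−3.57 ± 0.76, 0.328). The histocompatibility genes mhc1uka and mhc1uba had −4.73 ± 1.01 (0.339) and −6.30 ± 1.43 (0.392). The remaining named genes were adcy8 (2.14, 0.339), si:ch73-256j6.6 (1.43, 0.339), zgc:175107 (1.96, 0.387) and ftr51 (1.18, 0.447), and the 15 markers had adjusted p from 0.730 to 0.928.

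Of the lists, 17 were called for this difference by camera with the preset correlation, 6 higher and 11 lower in F2 relative to F1. The higher lists were the axoneme (median difference 1.54), spermatids and sperm (1.47), meiosis (1.40), the piRNA pathway (0.98), mitosis (0.93) and the proteasome (0.40). The lower lists were exocrine pancreas (−2.09), liver (−2.0), intestine (−1.29), erythrocytes (−1.14), macrophages (−0.96), complement and interferon (−0.74), smooth muscle and myoid (−0.41), immediate early genes (−0.40), matrix (−0.36), clock (−0.24) and ribosomal proteins (−0.16). The estimated correlation ran from 0.31 (clock) to 0.936 (exocrine pancreas) in these 17 lists, against the preset 0.01. With it the adjusted p was 0.703 for intestine, 0.709 for ribosomal proteins and 0.686 for the other 15. The median and the mean differed in sign for spermatogonia. By fry (smallest adjusted p = 0.670) and the exact permutation test (0.602) 0 lists were called. Without F1_TCDD replicate 3 the count was 26, and without F2_TCDD replicate 3 also 26. With the array set as a covariate it was 16. Without F1_TCDD replicate 2, 13 of the 17 were called, with the piRNA pathway (median 0.256), intestine (−0.326), smooth muscle and myoid (−0.204) and ribosomal proteins (−0.00476) lost, and the middle value of the medians went from 1.19 to 0.512 for the 6 higher and from −0.737 to −0.326 for the 11 lower lists. Without F1_DMSO replicate 5 ribosomal proteins (median 0.0274), the clock (−0.0994) and smooth muscle and myoid (−0.282) lost the call, and medians were −1.25 for liver, −0.845 for intestine, −0.251 for immediate early genes and −0.167 for matrix. Smooth muscle and myoid lost it also without F1_DMSO replicates 1 and 3, F1_TCDD replicate 5, F2_DMSO replicates 2 to 5 and F2_TCDD replicates 1, 4 and 5. Intestine lost it without F1_TCDD replicate 5, F2_DMSO replicate 4 (−0.525) and F2_TCDD replicates 1 (−0.906) and 5 (−0.972), macrophages without F1_TCDD replicate 5 and matrix without F2_DMSO replicate 3 (−0.206). The exocrine pancreas median was −0.923 without F2_TCDD replicate 1, and that of intestine −2.19 without F2_TCDD replicate 3. The ribosomal median ran from −0.330 without F1_TCDD replicate 5 to −0.0769 without F1_TCDD replicate 1 in the other cases that moved it. With the organ scores as covariates 3 of the 17 were called. Over all genes 0 members were called, and 1, of the complement and interferon list, when adjusted over the list alone.

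By limma 0 features were called for the difference between generations (4590 at an unadjusted p under 0.05, smallest adjusted p = 0.111). The count was 4 with the array set, 4 after quantile normalization, 3 after median centring and 52 with array weights. It was 6 without F1_TCDD replicate 2, 2 without F1_TCDD replicate 5, and 1 without each of F1_TCDD replicate 3, F1_DMSO replicate 2, F2_DMSO replicate 5, F2_TCDD replicate 1 and F2_TCDD replicate 4. Among the named genes mrps22 passed after quantile normalization (adjusted p = 0.0460), with array weights (0.0352) and without F1_TCDD replicate 2 (0.0371). With 1 probe set per gene, the one with the highest mean, 0 features were called by limma (smallest adjusted p = 0.575), so mrps22 did not pass there.

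Across all features, which are not independent replicates, the F1 and F2 log2 fold changes had a Pearson correlation of −0.150 and a Spearman correlation of −0.164, and 44.2% had the same sign. As large a Pearson correlation was found in 60 of 100 relabellings, the real one included. The value ran from −0.379 without F2_TCDD replicate 3 to 0.0683 without F2_TCDD replicate 1, and was 0.0560 without F2_DMSO replicate 4. No feature was called by limma in both generations. At an unadjusted p under 0.05, 82 features were higher in both and 79 lower in both, where independent lists give 65.3 and 45.0. Of the 72 features called in F2, 48 had the same sign in F1, and 18 had an unadjusted p under 0.05 in limma there, as did 5363 of all 75212 features.

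The DMSO lineages of both generations were compared as the background between generations. The otolith protein gene oc90 had lower values in F2 (9.34 ± 1.52 in F1, 3.86 ± 0.19 in F2, n = 5), with a log2 fold change of −5.48 ± 0.88 (adjusted p = 0.00360). The class II histocompatibility gene mhc2daa was at 4.44 ± 1.87 in F1 and 10.30 ± 0.45 in F2, a difference of 5.86 ± 1.25 (adjusted p = 0.00588). The parvalbumin gene pvalb4 was at 7.73 ± 0.58 and 11.67 ± 1.43 (3.94 ± 0.78, adjusted p = 0.00474). Among germ cell markers sycp3 had −2.03 (adjusted p = 0.0220) and zp3b −1.55 (0.0223), and cyp17a1 of steroid synthesis had −1.99 (0.0285). List scores, array set removed, differed as well. In F1 and F2 DMSO arrays they were 0.725 ± 0.14 and −0.21 ± 0.507 for meiosis and −1.58 ± 1.62 and 1.21 ± 0.96 for exocrine pancreas. Camera called 17 lists here with the preset correlation, 14 higher and 3 lower, and 0 with an estimated one.

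Other named genes lower in F2 were LOC793824 (−3.37 ± 0.61, adjusted p = 0.00403), the radial spoke gene rsph4a (−3.37 ± 0.73, 0.00606), pimr195 (−3.32 ± 0.66, 0.00488) and rab36 (−3.23 ± 0.82, 0.0108). Higher were zgc:103700 (5.17 ± 1.27, 0.00954), the ileal bile acid binding gene fabp6 (4.49, 0.0343) and fbp2 of gluconeogenesis (4.31 ± 0.97, 0.00709). These 7 genes, with oc90, mhc2daa and pvalb4, kept their direction and call after quantile normalization and after median centring, while sycp3 and cyp17a1 lost the call in both and zp3b after quantile normalization. With the array set as a covariate none of the 13 was called (adjusted p from 0.361 to 0.955), which does not show that the differences were absent, since the lower set holds 1 F1 control array. The log2 fold change was then −3.37 ± 1.08 for oc90, 2.54 ± 1.47 for mhc2daa, 2.92 ± 1.09 for pvalb4, 3.25 ± 1.39 for fbp2, 4.13 ± 1.84 for zgc:103700 and 2.2 ± 2.09 for fabp6. It was −1.61 for LOC793824, −1.96 for rsph4a, −1.69 for pimr195, −1.75 for rab36, −1.18 for sycp3, −1.39 for cyp17a1 and −0.0916 for zp3b. The gene fabp6 belongs to the intestine list, whose mean score, array set removed, was −0.867 in F1 and 0.288 in F2 DMSO arrays. For skeletal muscle these scores were −0.533 and 0.974.

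In all, 20778 features were called, 2264 higher and 18514 lower in F2, and the median log2 fold change of all features was −0.339. After quantile normalization, which moved that median to 0.0161, 12716 were called (6739 higher, 5977 lower), and after median centring (median −0.0207) 12967 (5695 higher, 7272 lower). With the array set as a covariate 3 were called, and within the 12 arrays of the lower set, which hold 1 F1 control array, 36. With array weights 42916 were called. The counts were 13178, 13113, 12428 and 11625 without F1_DMSO replicates 1, 2, 3 and 4.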

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

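The tests of explanations for the F1 lists were chosen after the result was seen, while the comparison with other splits of the samples was chosen before. A list score or gene is named here where 1 array stood apart from the rest of its group by Dixon's test at 95%, run in F1 over the 4 arrays of the higher set and in F2 over 5. It was applied to the scores of 39 lists, the 11 named genes called in F2 and 15 markers. Of 260 cases 24 were beyond the limit, where chance gives about 13 (1 in 20).

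F1_TCDD replicate 2 held 12 of the 24, with low values of testis genes. The gap to the nearest array, as a share of the group's range, was 0.976 for gsdf (7.78 against 13.29), 0.942 for the Leydig cell hormone gene insl3 (5.72 against 12.22), 0.924 for the germ cell gene ddx4 (7.37 against 12.18), 0.913 for star (7.21 against 11.63) and 0.909 for amh (6.34 against 11.79). It was 0.895 for cyp11c1, 0.888 for cimap1b and 0.83 for tekt1, all lowest in that array, and 0.867 for cmtm6, which was highest there. Of the list scores in that array, Sertoli cells had 0.926, the piRNA pathway 0.871 and Leydig cells 0.844, all lowest.

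The flags in the other arrays were about as many as chance gives (about 13 over all 260 cases), so each of them may be chance. Among these the score of exocrine pancreas was highest in F1_DMSO replicate 1 (0.858), as was LOC100002043 (0.894, 6.60 against 5.44). The proteasome score was highest in F1_DMSO replicate 4 (0.884). Retinoid scores stood apart in F1_DMSO replicate 3 (0.835) and F2_TCDD replicate 1 (0.918), Leydig cells in F2_DMSO replicate 3 (0.862), and smooth muscle and myoid in F2_DMSO replicate 1 (0.888). In F2_TCDD replicate 3 the scores of adipocytes (0.758), cholesterol synthesis (0.787) and fatty acid metabolism (0.793) did, and in F2_DMSO replicate 4 those of the respiratory chain (0.71) and of heat shock (0.728).

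The lineage difference of 17 lists differed between F2 and F1 by camera with the preset correlation, but for 0 by camera with an estimated correlation, by fry or by the exact permutation test. Adjusted p with the preset correlation was 8.955e-13 for the axoneme, 8.506e-08 for spermatids and sperm, 4.698e-06 for mitosis, 2.801e-05 for meiosis, 3.185e-05 for the proteasome and 0.0004036 for the piRNA pathway, which were higher in F2 relative to F1. Among the lists that were lower it was 4.698e-06 for complement and interferon, 2.505e-05 for liver, 0.0002219 for exocrine pancreas, 0.0002411 for erythrocytes and 0.0003865 for immediate early genes. It was 0.001408 for matrix, 0.003255 for macrophages, 0.005315 for ribosomal proteins, 0.0054 for the clock, 0.0133 for intestine and 0.03648 for smooth muscle and myoid. As many lists were called in 54 of 100 splits of the samples, the highest other being 32, so chance cannot be excluded.

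Low germ cell lists beside high organ lists in F1 may come from tissue of neighbouring organs in some samples, since within groups the intestine score ran against the meiosis score over 20 arrays (Pearson r = −0.75, permutation p = 3e-05, adjusted p = 0.00024 over 8 relations; Spearman rho = −0.792, permutation p = 6e-05). By the count set first, 17 lists were called with the organ scores as covariates, under 1/1.5 of the 28, and in a count added after that had been seen 16 of the 25 outside the organ lists stayed called. These counts do not decide on organ tissue, since other splits of the samples called 19 lists at the median and up to 31. Organ tissue as the source of the lower lists stays open by a further measure added then, since 7 of the 8 stayed called while the middle value of their medians went from −0.924 to −0.405. A large part of the size of the lower lists rested on F1_TCDD replicate 2, without which that value was −0.315 and in which 11 of 11 testis markers were lower than in the other 19 arrays, as in a sample with little testis tissue or with a wrong label, while the 23 lists called without it do not decide on the calls, since other splits called up to 31. Ancestral TCDD cannot be told apart from the spread between males (smallest adjusted exact p = 0.499 with 5 arrays per group, where at least 12 lists with a low exact p are needed for any to pass). Chance cannot be excluded either, since as many lists as the 28 were called in 15 of 100 splits.

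The correlation was −0.747 without the 2 farthest arrays, −0.870 without F1_TCDD replicate 2 and −0.895 in the lower set of 12 arrays (−0.756 there without the 2 farthest). In the higher set of 8, which holds F1_TCDD replicate 2, it was −0.791 (permutation p = 0.00625, adjusted p = 0.0207), and −0.594 without the 2 farthest. Spearman rho in the higher set was −0.738 (permutation p = 0.0458, adjusted p = 0.132). Over the 20 arrays the intestine score had r = 0.75 with liver (adjusted p = 0.000533), 0.593 with exocrine pancreas (0.00922), −0.719 with spermatids and sperm (0.00052), −0.579 with Sertoli cells (0.00922), −0.40 with Leydig cells (0.104), 0.121 with matrix (0.698) and 0.0894 with skeletal muscle (0.708), all from permutation tests. Abundant genes, of which anpepb.1, fetub and prss59.2 were chosen after their values were seen, spanned wide ranges over the arrays, from 6.65 to 12.67 for cdh17 and 5.29 to 12.92 for anpepb.1 of intestine, 6.66 to 13.66 for fetub of liver and 9.25 to 14.33 for prss59.2 of pancreas. Of the 14 intestine, 21 liver and 15 pancreas genes 1, 1 and 0 were in another list, and 3, 9 and 11 lay above the array median on every array.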

How the results depend on the processing

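The array set, fits within a set, the organ scores, the fit without the 4 arrays with the highest intestine score, identical rows counted once and the permutation test were tests chosen after the data were seen. In F1 the count of 0 became 1 after median centring, 1 with the replicate block, 7 with array weights and 3204 at an unadjusted p under 0.05 with a fold of 1.5. In F2 the count of 72 became 139 at an adjusted p under 0.10, 2065 at the unadjusted p with a fold, 504 with array weights and 44 with the replicate block (30 of them among the 72). It was 120 with the array set, 105 with the organ scores and 136 without the 4 arrays. With 1 probe set per gene it was 5, a fit that the 61 called features without a symbol could not enter, while 11 had 1 symbol. With identical rows counted once it was 48. For the difference between generations the count of 0 became 4041 at the unadjusted p with a fold, 4 after quantile normalization, 3 after median centring, 52 with array weights, 2 with the replicate block, 4 with the array set, 6 with the organ scores and 1 without the 4 arrays. Between the DMSO lineages the count of 20778 became 5772 with 1 probe set per gene, 12716 after quantile normalization, 12967 after median centring, 42916 with array weights, 3 with the array set, 36 within the lower set, 0 by limma with the organ scores and 3 without the 4 arrays. Of the lists, the 28 called in F1 became 3 with array weights, 18 within the higher set, 17 with the organ scores, 12 without the 4 arrays, and 0 with an estimated correlation, fry or the exact permutation test, as did the 8 in F2. In the permutation test at least 12 lists in F1 and 7 in F2 need a low exact p for any to pass, so it is weak where few lists differ. Exact p were under 0.05 for 1 list in F1 and 0 in F2. The 17 called for the difference became 11 with array weights, 6 with the organ scores and 0 with an estimated correlation, fry or the exact permutation test. Leaving out 1 array gave 0 to 1 calls in F1, 31 to 118 in F2, 0 to 6 for the difference (lists 15 to 26) and 11625 to 29215 between the DMSO lineages.

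The cause was not tested unless named. Replicate numbers were not taken as pairs, since the labels state no pairing and not every same-numbered pair deviated together (r over 0.1 in 4 of 5 pairs in F1 and 3 of 5 in F2). Pairing stays possible, since an array's best partner had its own number for 4 of 5 in F1 and 2 of 5 in F2, although both F1 replicates 5 share an array set. With the block pde6ha (adjusted p = 0.113), coq7 (0.113) and ccdc86 (0.152) were not called in F2. With the replicate block the lists called were 27, 9 and 22, and 21416 features between the DMSO lineages. Of 1332 values of named genes in F2 over all settings, 1249 kept direction and side of the threshold, 58 lost the call, 1 gained it and 24 that were not called changed sign. In F1 3049 of 3077 were kept, between generations 758 of 773 and between the DMSO lineages 459 of 575. The last had 1 called value that turned, zp3b at 0.0201 with the array set and without the 4 arrays. The signal over background of the arrays is not given in the sources used here.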

Other observations

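The tests of explanations for the F2 calls and for the DMSO lineages were chosen after the results were seen, while the comparisons with other splits of the samples were chosen before. The histocompatibility genes mhc1uba and mhc1uka were chosen here after their values were seen. The class I gene mhc1uba was at 4.13 to 4.85 in all 5 F2_TCDD arrays, and at 8.65 to 9.67 in 4 F2_DMSO arrays but 4.53 in F2_DMSO replicate 4. In F1 it was at 7.40 to 9.94 in TCDD and 3.71 to 9.42 in DMSO arrays. It did not pass in F2 (adjusted p = 0.295), with 0.0513 without F2_DMSO replicate 4 and 0.0352 with array weights. The class I gene mhc1uka was at 4.91 to 5.59 in F2_TCDD, 5.61 to 9.33 in F2_DMSO, 8.30 to 11.39 in F1_TCDD and 5.03 to 8.65 in F1_DMSO arrays.

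Features called in F2 were large steps, and part of them were close to each other in the table. Of the 35 distinct called features in the identifier range of named features, 14 had another within 20 positions, where 1000 random draws gave at most 9 and the top features of 99 other splits at most 12. Neighbours may be probe sets of 1 transcript, so those within 5 positions that went the same way were counted as 1, a measure added after the first count had been seen. Then 2 of 27 had a neighbour, as did as many in 52 of the 99 splits. That measure went by position and direction alone, so it also joined LOC100006764, LOC100006805 and LOC100006875, which have different gene symbols and all fell. In that range 98.2% of consecutive named features lay on 1 chromosome, and the largest run held 6 features, with LOC100006764, LOC100006805 and LOC100006875.

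A candidate explanation is linked sequence differences between the F2 families. The 14 neighbours do not decide on it, since some may be probe sets of 1 transcript. Nor do the 2 left when neighbours that went the same way were counted as 1, since that count also joined genes with different symbols. Kinship is not given in the sources used here. Tissue of neighbouring organs stays open in part. With the organ scores added 105 features were called (54 higher, 51 lower). Of the 120 features called with the array set, 60 were among them, below the limit of 1/1.5 that had been set first. A second measure, added after the count of 60 had been seen, argues against organ tissue as the whole cause of the fold changes. The median size of the 120 was 1.79 before and 1.76 after, all 120 with the same sign, at a median SE of 0.299 and 0.2801. Why the other 60 lost the call was not tested. For the called features as a set, an ancestral effect of the same size in F1 is argued against by a mean of 0.356 in the F2 direction there against 2.28 in F2. The F2 mean is inflated, because the features were chosen by their F2 values. A smaller effect stays open (exact p = 0.0286 over 140 assignments, 33 of 51 with the same sign). Single features may still share it, such as the unnamed probe set 13213342 with 2.93 in F1 and 3.65 in F2. As many calls as the 72 were found in 1 of 100 splits, the real one, the highest other being 31, so a chance split of the males is excluded at that level, but not a difference between families.

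Calls over a large part of the array between the DMSO lineages may come from the 2 array sets, since 3 of 20778 calls were left with the set as a covariate (median fold change 0.952 before and 0.330 after, at a median SE of 0.265 and 0.282) and 22828 features differed between the sets inside F1. A shift of whole arrays accounts for part by the limit of 1/1.5 set first, with 12967 calls after median centring. By a stricter limit of 1/10, added after that count had been seen, it is argued against as the whole cause. As many calls were found in 1 of 100 splits, the real one, but the highest other had 13263, and splits with so many calls point to a structure of the samples. Generation itself stays open, since only 1 F1 control array lies in the lower set. So does tissue of other organs, which the 0 calls with the organ scores do not decide, since 3 were left with the array set alone. Mean scores in F1 and F2 DMSO arrays, array set removed, were −1.58 and 1.21 for exocrine pancreas, −0.533 and 0.974 for skeletal muscle and 0.725 and −0.21 for meiosis.

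For the lists called in F2 and the correlation between generations chance cannot be excluded. The 8 lists called in F2 were matched by 95 of 100 splits (highest other 31), and the size of the correlation between generations by 60 (highest other 0.718). A count of 0 is matched by every split and decides nothing, as for the 0 calls by limma in F1 (100 of 100 splits, highest other 11) and for the difference between generations (100 of 100, highest other 4).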
